A study of Danio rerio with 6 samples.

How the data were processed

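RNA was measured in 6 libraries of sorted cells from zebrafish embryos at 48 hours after fertilisation, 3 from wild-type fish and 3 from fish carrying the uq4bh mutation of mafba. The labels give the transgene as kdrl driving EGFP, which marks endothelial cells, and call the samples purified endothelial cells. The labels' protocol also speaks of dissociated brains and of pdgfr beta EGFP-positive cells, which differs from the transgene and source fields. Which tissue was dissociated and which reporter set the gate are therefore not settled by the labels. RNA was amplified before sequencing, per the labels' protocols.

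The values deposited by the authors are whole-number counts of reads per gene symbol, not normalised, in one file per library. The tools named are bcl2fastq, STAR and HTSeq and the genome builds danRer7 and Zv9, per the submitters' processing notes. The versions, the gene annotation and the strand setting are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart, and genes with near-identical copies, such as globins and keratins, carry an uncertain share of reads. Each file lists 29361 gene symbols and ends with 5 summary rows for reads outside genes. These rows hold 22.1% to 28.1% of the entries of each file, and were left out of library sizes and tests. A table of the whole series held the same counts gene by gene.

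Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and plots were drawn in Python 3.11.15 with matplotlib 3.10.9. Reads assigned to genes ranged from 43859736 to 52923490 per library. Low-count genes were removed with the default settings of filterByExpr on both groups, which left 19381 genes, and libraries were scaled with TMM factors. Mutant libraries were compared with wild-type libraries by the edgeR quasi-likelihood test with robust fitting, with no block, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Levels are given as CPM, that is gene counts relative to the TMM-scaled library size, and differences as log2 values, mutant minus wild-type, with standard errors (SE) and 95% confidence intervals. Where every library of one genotype held 0 reads, the fold is a lower bound against 3 reads summed over that genotype. Intervals of counting error and such bounds do not cover amplification. The bounds rest on reads summed within a genotype and do not cover the spread between libraries, which the fitted 95% intervals do. Nothing in the labels says that the 3 libraries of a genotype came from separate pools of embryos, so p-values measure the spread between these libraries, which may be technical.

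Lists of genes were tested with camera at a preset inter-gene correlation of 0.01 on log2 CPM with a prior count of 2, then again with an estimated correlation, and with fry for shifts in one direction and for mixed changes. The 25 lists cover endothelial, signalling, stress and cell type markers. Of 662 list entries, 589 matched a symbol in the files, 21 matched through a synonym in a reference table of gene names of the assembly GRCz12tu, and 52 had no match. Coordinates were not used here, because that table and the counts rest on different builds. The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule names mafba and each detected Maf family gene, 9 endothelial and lymphatic genes, up to 24 genes past the threshold, and in each list the members past the threshold or otherwise the 2 with the smallest p. No gene passed, so the genes named from lists are given as values.

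The tests were tested on simulated data drawn from the means, fitted dispersions and library sizes of these 6 libraries. Of 18135 genes, 200 were changed, and the 30 genes of the list described below were shifted as well. For the comparison of mutant with wild-type libraries, the edgeR quasi-likelihood test recovered 26.9% of genes changed 2-fold, 83.6% of those changed 4-fold and 97.0% of those changed 8-fold, with 11 false calls. DESeq2 recovered 40.3%, 89.6% and 97.0% with 64 false calls, and limma-voom 26.9%, 77.6% and 81.8% with 10 false calls. A simulated list of 30 genes shifted 2-fold reached an adjusted p of 2.0e-25 with the preset and 0.00549 with the estimated correlation in camera, and 0 of 20 unshifted lists were called. Each gene was drawn independently, so list members did not vary together. The simulation therefore cannot show how camera treats members that do. It also held no differences between libraries that cut across genotype, so the shares recovered may not carry over to the real libraries. Genes with low means were left out of those changed. The alternatives were other scalings, other low-count filters, DESeq2, limma-voom with sample quality weights, fitting without robust estimation and a replicate block. Further ones were other thresholds, a minimum fold of 1.5, the same counts read from the table of the whole series, and leaving out each library in turn.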

Results

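Sequencing of sorted cells from 48-hour zebrafish embryos gave 3 wild-type and 3 mafba mutant libraries, with 43859736, 44629391 and 49145191 reads on genes in wild-type 1, 2 and 3 and 49197402, 44888870 and 52923490 in mutant 1, 2 and 3. The cells are labelled as endothelial cells carrying a kdrl reporter, although the protocol text also mentions brains and a pdgfr beta reporter. Between 19230 and 21098 genes were detected per library. The question addressed was which genes depend on mafba, a transcription factor of the large Maf family, in the endothelium during the period in which lymphatic vessels begin to form.

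The RNA level of mafba itself differed between the genotypes by less than the spread between replicates. It stood at 32.9, 45.8 and 33.3 CPM in the wild-type libraries and 31.0, 39.6 and 38.6 CPM in the mutant libraries, with means of 37.3 ± 7.35 and 36.4 ± 4.73 CPM (SD, n = 3 each). The log2 difference was -0.04 ± 0.20 (SE), with a 95% interval of -0.47 to 0.40, that is from 0.721 to 1.32 times the wild-type level. The sign changed when wild-type 2 (0.14) or mutant 1 (0.07) was left out. The position of the uq4bh lesion is not given in the sources used here, so the RNA level does not check the genotype labels.

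Other Maf genes were also detected. The paralogue mafbb stood at 31.4 ± 2.78 CPM in wild-type and 23.1 ± 8.02 CPM in mutant libraries (SD, n = 3), a log2 difference of -0.44 ± 0.25 (SE). For mafa the difference was -0.59 ± 0.50, for maf 0.06 ± 0.46, for maff 0.09 ± 0.16, for mafgb 0.62 ± 0.54 and for mafk -0.17 ± 0.38. Both mafga and nrl lay below the low-count filter. Of the 7 tested Maf genes, 0 passed the edgeR quasi-likelihood test over all genes and 0 when adjusted over the list alone.

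Endothelial and lymphatic genes were detected in both genotypes, and none of the 9 chosen in advance passed the test. The Vegf receptor gene kdrl stood at 42.3 ± 10.9 and 39.4 ± 5.04 CPM, and cdh5, which encodes VE-cadherin, at 15.7 ± 1.03 and 13.9 ± 3.28 CPM (wild-type and mutant, SD, n = 3). The log2 differences were -0.10 ± 0.21 and -0.17 ± 0.26 (SE). The gene for the Vegfc receptor, flt4, differed by 0.27 ± 0.34, and the lymphatic transcription factor gene prox1a by 0.00 ± 0.28, a value whose sign turned under other scalings. The venous and lymphatic scavenger receptor genes stab1 and stab2 differed by -0.10 ± 0.27 and -0.11 ± 0.26, lyve1b by -0.61 ± 0.47 and mrc1a by -0.48 ± 0.32. The ligand gene vegfc was low in all libraries, at 1.85 ± 1.26 and 0.911 ± 0.340 CPM, and its log2 difference of -1.02 had a 95% interval of -2.98 to 0.94.

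**Figure D1:**
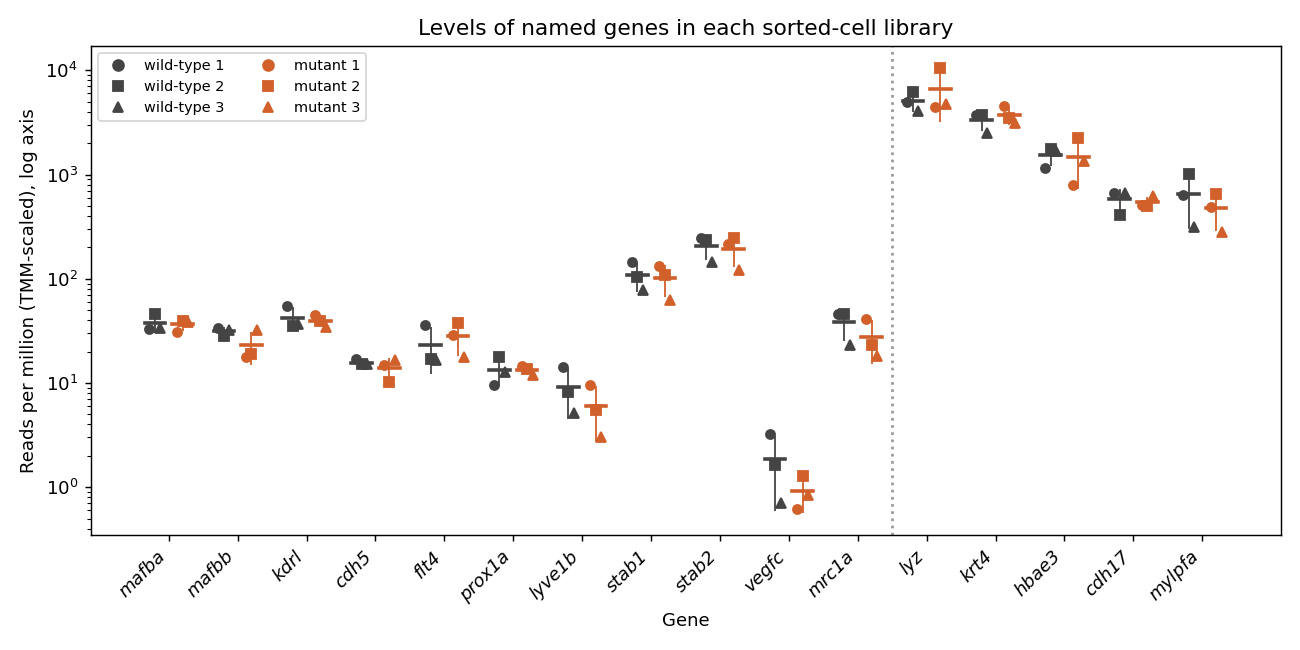
Levels of 16 genes in each library, in CPM (reads relative to the scaled library size) on a log axis, with wild-type in grey and mutant in orange, horizontal bars at the group mean and vertical lines of 1 SD (n = 3). Left of the dotted line are Maf, endothelial and lymphatic genes, and right of it markers of other cell types, which all stand above kdrl (42.3 and 39.4 CPM).

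Across the transcriptome, no gene passed. The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 19381 genes, 0 higher and 0 lower, with 305 genes at an unadjusted p under 0.05 where 969 would arise by chance. DESeq2 also called 0 genes, with 358 at an unadjusted p under 0.05, 35 without an adjusted p and a lowest adjusted p of 0.0829, and limma-voom called 0, with 461. The biological coefficient of variation was 0.578. The precision differed with expression: the median half-width of the 95% interval was 1.31-fold for the 4245 genes with a mean log2 CPM over 5, 1.60-fold for 7723 genes from 2 to 5, 3.01-fold for 4175 genes from 0 to 2 and 21.6-fold for 3238 genes under 0. Libraries of one genotype correlated at 0.873 to 0.915 across genes (mean 0.894) and libraries of different genotypes at 0.866 to 0.937 (mean 0.897), with genes not being independent replicates.

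**Figure D2:**
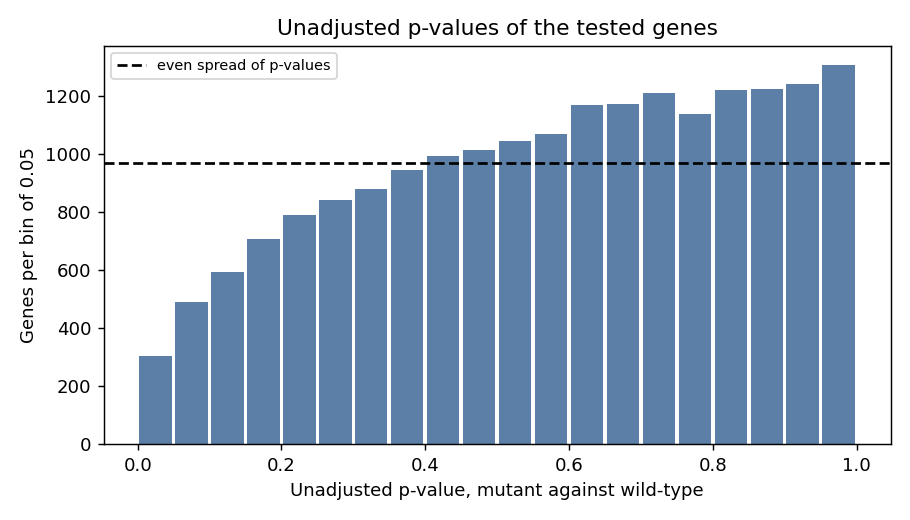
Number of genes in each bin of 0.05 of the unadjusted p-value of the edgeR quasi-likelihood test, with a dashed line at the 969 genes per bin of an even spread. The first bin holds 305 genes and the last 1309.

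Among the lists of vessel identity, the members were divided between higher and lower fitted values and 0 genes passed in any list, over all genes or adjusted over the list alone (edgeR quasi-likelihood). In the pan-endothelial list 11 of 30 members were fitted higher and 19 lower (median log2 difference -0.08). Its members with the smallest p were s1pr1, a receptor for sphingosine-1-phosphate, at -0.39 ± 0.16 (SE), and the haematoendothelial factor gene tal1 at -0.44 ± 0.21. In the lymphatic and Vegfc pathway list 14 of 24 were higher and 10 lower (median 0.03), with adamts3, whose protease takes part in Vegfc processing, at 1.53 ± 0.77 and cdh6 at -0.58 ± 0.33. In the venous list 7 of 14 were higher and 7 lower (median -0.02), led by ephb4a at 0.31 ± 0.21 and mrc1a. In the arterial list 6 of 21 were higher and 15 lower (median -0.03, mean -0.24), with alcama at 0.51 ± 0.20. A gap junction gene of this list, cx41.8, had 14, 43 and 20 reads in the wild-type libraries and 0 in each mutant library. Summed reads alone put it at least 27.5-fold lower (at least 17.8-fold without wild-type 2 and 16.6-fold without mutant 3). Its fitted confidence interval, which covers the spread between libraries, reached up to 0.483 times the wild-type level. The list median with this gene at its bound was also -0.03.

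The members of the signalling lists were also divided. In the list of tip cell, chemokine and guidance genes 16 of 26 were fitted higher and 10 lower (median 0.05), with robo1, a Slit receptor, at -0.53 ± 0.25 and itgb3a at 0.86 ± 0.47. In the Notch list 10 of 25 were higher and 15 lower (median -0.02), with the Notch target hey1 at 0.63 ± 0.26 and the ligand gene dla at -0.39 ± 0.26. In the BMP and flow response list 8 of 21 were higher and 13 lower (median -0.12), with the flow-responsive klf2b at -0.38 ± 0.19 and smad9 at 0.68 ± 0.35. The brain endothelium and Wnt list had 7 higher and 7 lower of 14 (median 0.02), with the Wnt pathway genes axin2 at -0.41 ± 0.22 and lef1 at 0.32 ± 0.24. In the basement membrane and matrix list 14 of 29 were higher and 15 lower (median -0.02), with the collagen genes col18a1 at 0.51 ± 0.19 and col8a1a at -0.85 ± 0.43. The Maf family list had 3 higher and 4 lower (median -0.04).

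Of the lists of cell state, proliferation had 23 of 36 members higher and 13 lower (median 0.04), with the mitotic genes kif11 at 0.27 ± 0.14 and cdc20 at 0.20 ± 0.17. The p53 and unfolded protein response list had 15 of 25 higher and 10 lower (median 0.02), with sesn1 at -0.28 ± 0.18 and phlda3 at -0.31 ± 0.23. In the dissociation stress list 14 of 26 were higher and 12 lower (median 0.01), with the heat shock genes hspb1 at -0.64 ± 0.34 and hsp90aa1.1 at -0.76 ± 0.47. In the list of haemogenic genes near the kdrl reporter's range 4 of 11 were higher and 7 lower (median -0.03), with lmo2 at -0.43 ± 0.21 and tal1. The sign of the median, the mean and the camera test differed within the Notch, BMP and flow response, dissociation stress, and macrophage and microglia lists.

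Some genes used as markers of blood, skin, muscle and kidney cells stood above kdrl in every library of both genotypes, while other members of the same lists, such as gata1a (16.8 and 9.26 CPM), myod1 (2.11 and 0.835 CPM) and hnf1ba, stood below it. The neutrophil gene lyz reached 5095 ± 1073 CPM in wild-type and 6575 ± 3392 CPM in mutant libraries, the keratin gene krt4 3332 ± 712 and 3714 ± 730, the embryonic globin gene hbae3 1539 ± 325 and 1459 ± 726, the muscle myosin light chain gene mylpfa 653 ± 350 and 478 ± 188, and the kidney cadherin gene cdh17 581 ± 146 and 542 ± 68.5 (SD, n = 3). These genes, like pdgfrb, were chosen for naming after their values were seen, except lyz. The pericyte receptor gene pdgfrb was at 0.410 ± 0.358 and 0.715 ± 0.425 CPM.

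Of the lists of other cell types, skeletal muscle and neural genes were fitted lower in the mutant libraries. In the skeletal muscle list 30 of 36 members were lower and 6 higher (mean log2 difference -0.36), and in the neural list 27 of 35 were lower and 8 higher (mean -0.21). Both had an adjusted p of 0.0159 in camera with the preset correlation, and both had an adjusted p of 0.975 with an estimated correlation. None of the members passed singly (edgeR quasi-likelihood, 0 over all genes and 0 adjusted over the list alone), the smallest p being those of myod1 at -1.33 ± 0.83 and tnni2b.1 at -0.73 ± 0.47 in muscle, and crx at -0.64 ± 0.29 and fabp7a at -0.33 ± 0.15 in the neural list. The muscle score of the wild-type libraries was 0.26, 0.87 and -0.58 and of the mutant libraries -0.24, 0.39 and -0.70 log2 units, so wild-type 3 lay below 2 of the 3 mutant libraries. The dissociation stress score put the 6 libraries in the same order, at -0.09, 0.37 and -0.20 in wild-type and -0.12, 0.27 and -0.24 in mutant libraries. In both scores that order ran by library number, 2 then 1 then 3, with wild-type above mutant within each number. The labels tie the numbers to nothing shared. Leaving out wild-type 2 gave a muscle mean of -0.02, leaving out mutant 3 gave -0.11 and leaving out wild-type 1 gave -0.32, with adjusted p-values of 0.945, 0.724 and 0.157 in camera. Leaving out wild-type 3 or mutant 2 gave larger muscle means of -0.75 and -0.65. The neural list lost its call without wild-type 2 (-0.19, adjusted p = 0.312), wild-type 3 (-0.16, adjusted p = 0.207) or mutant 1 (-0.06, adjusted p = 0.517) in camera.

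**Figure D3:**
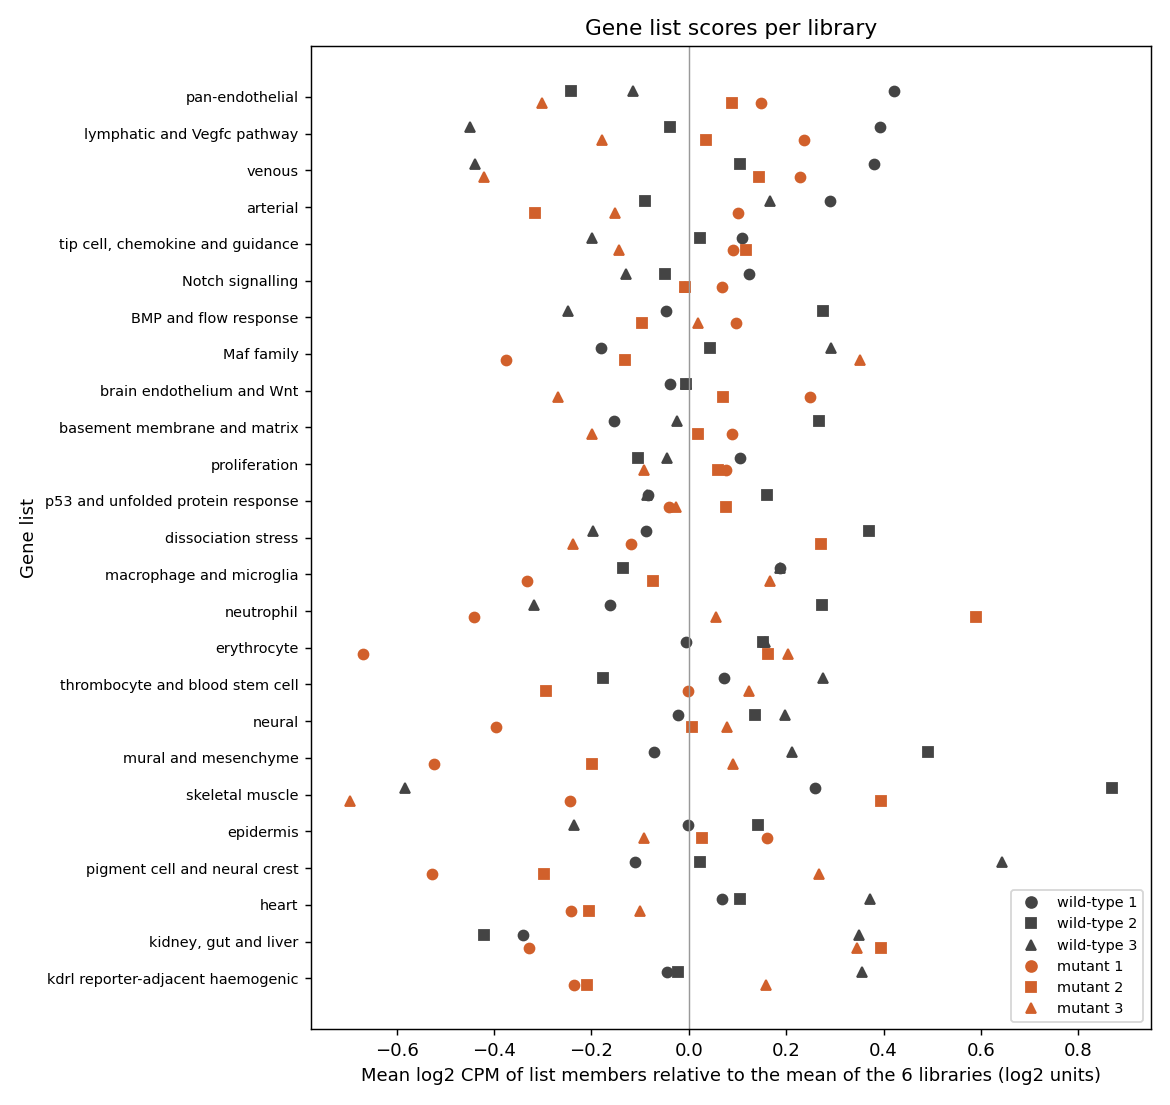
Score of each of the 25 lists per library, the mean log2 CPM of its members relative to the mean of the 6 libraries, with wild-type in grey and mutant in orange. In the skeletal muscle list wild-type 2 stands highest (0.87) and mutant 3 lowest (-0.70), and the genotypes overlap.

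The other cell type lists were not called by camera. In the macrophage and microglia list 15 of 30 members were higher and 15 lower (median 0.01), with the macrophage gene mfap4 at -1.21 ± 0.65 and c1qb at -4.43 ± 2.51. Of 14 neutrophil genes 12 were higher and 2 lower (median 0.16), with mpx at 0.41 ± 0.31 and lyz at 0.37 ± 0.30, both of which turned negative without mutant 2. Of 22 erythrocyte genes 8 were higher and 14 lower (median -0.10), with the transcription factor gene gata1a at -0.85 ± 0.35 and sptb at -0.27 ± 0.23. The thrombocyte and blood stem cell list had 6 higher and 9 lower of 15 (median -0.27), with meis1 at 0.28 ± 0.17 and itgb3a. In the mural and mesenchyme list 10 of 29 were higher and 19 lower (median -0.30, mean -0.42), with fbn2b at 0.57 ± 0.23 and pdgfra at -1.20 ± 0.53. Of 36 epidermis genes 18 were higher and 18 lower (median 0.01), with fras1 at 0.46 ± 0.21 and apoc1l at 1.80 ± 0.95. The pigment cell and neural crest list had 9 higher and 10 lower of 19 (median -0.02, mean -0.37), with the iridophore gene pnp4a at -3.42 ± 1.32 and the xanthophore gene aox3 at -1.48 ± 0.84. The heart list had 3 higher and 8 lower of 11 (median -0.26, mean -0.36), with nfatc1 at -0.34 ± 0.28 and vmhcl at -1.09 ± 1.07. Its scores were 0.07, 0.11 and 0.37 in wild-type and -0.24, -0.21 and -0.10 in mutant libraries, and it was the 1 list of 25 that reached the smallest exact permutation p of 0.1 that this design allows (two-sided). Over 25 lists such a value can arise by chance. The heart list was low, at a median percentile of 18.8, and its summed CPM overlapped between genotypes (58.8, 114 and 63.2 in wild-type, 73.6, 59.5 and 69.5 in mutant libraries). In the kidney, gut and liver list 12 of 21 were higher and 9 lower (median 0.08, also with apobb at its bound). Its transcription factor gene hnf1ba stood at 8.58 ± 1.95 and 16.5 ± 3.05 CPM (SD). The log2 difference of hnf1ba, 0.94 ± 0.28 (SE), did not pass. The apolipoprotein gene apobb had 10, 24 and 21 reads in wild-type and 0 in each mutant library. Summed reads alone put apobb at least 19.7-fold lower (11.8-fold without mutant 3). Its fitted confidence interval reached up to 0.912 times the wild-type level. The mixed test of fry asks whether members change in either direction. It called the kidney, gut and liver list (adjusted p = 0.0128) and the arterial list (adjusted p = 0.0387). Its directional test called 0 of the 25 lists (lowest adjusted p = 0.993). In each of the 2 called lists 2 members had an unadjusted p under 0.05 (edgeR), including apobb and cx41.8, which had few reads. The lowest edgeR p adjusted over the list alone was 0.116 and 0.289. Other splits of the libraries were not put to the mixed test.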

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

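The test of the replicate block with an estimated correlation and the comparison of list scores within same-numbered libraries were chosen after the results were seen, and the other alternatives before. The number of changed genes was 0 in edgeR under each alternative scaling, filter, threshold, minimum fold and left-out library, in DESeq2 and in limma-voom, where the main edgeR test had 305, DESeq2 358 and limma-voom 461 genes at an unadjusted p under 0.05. The lowest adjusted p in these was 0.0829, in DESeq2. Of 960 alternative values for the 61 named genes, 931 had the sign of the main value, 29 in 12 genes had the other, and 0 passed the threshold (lowest adjusted p 0.767). The value of prox1a, 0.00 in the main test, was -0.004792 with RLE factors, -0.01041 with upper-quartile factors, -0.002744 with library totals, -0.001162 without a filter, -0.007978 with the strict filter and -0.004807 in DESeq2, and maf was -0.08422 in limma-voom. With each library left out in turn, mafba ranged from -0.12 to 0.14, maf from -0.24 to 0.38, maff from -0.001145 to 0.25, mafk from -0.43 to 0.18, kdrl from -0.22 to 0.13, cdh5 from -0.32 to 0.007449, prox1a from -0.18 to 0.26, stab1 from -0.34 to 0.16, stab2 from -0.31 to 0.14, hsp90aa1.1 from -1.15 to 0.03734, mpx from -0.002117 to 0.73 and lyz from -0.14 to 0.58. Among the 59 named genes with reads in both genotypes, 8 moved by over 1.5-fold in some of these fits: hsp90aa1.1, c1qb, which had reads in 1 mutant library, apoc1l (0.74 to 2.27), aox3 (-2.02 to -0.56), vmhcl (-1.88 to -0.67), mfap4 (-1.71 to -0.52), vegfc (-1.41 to -0.36) and mafgb (0.34 to 1.25). The number of shifted lists ranged from 0 to 3, the skeletal muscle mean from -0.75 to -0.01998 and the neural mean from -0.30 to -0.06105. With an estimated correlation 0 lists were shifted, at the same means of -0.36 for muscle and -0.21 for neural genes. The cause was not tested for any of these changes. With the replicate number as a replicate block, 0 genes were called (lowest adjusted p 0.0535) and 523 had an unadjusted p under 0.05, maf was -0.0391, mafba -0.03, and both lists were called (adjusted p 5.6e-06 and 0.00873, camera with the preset correlation), while the replicate block with an estimated correlation gave 0 lists (lowest adjusted p 0.949). Deviations of same-numbered libraries (numbers 1, 2 and 3) correlated at 0.0598, 0.0211 and 0.140 across all tested genes, where wild-type 1 and mutant 2 did not correlate best with their own number, and at 0.347, 0.112 and 0.537 across the 4245 genes with a mean log2 CPM of at least 5, where only mutant 2 did not. The labels tie the numbers to nothing shared, and whether they pair the libraries depends on the genes used. Within each of the 3 same-numbered pairs the mutant score was lower for muscle (-0.50, -0.48 and -0.11) and neural genes (-0.37, -0.13 and -0.12), as it was in 9 of the 25 lists, against 0 higher in each pair, and an exact sign-flip test of 3 pairs cannot give a two-sided p under 0.25. No filter kept 23505 genes and the strict filter 11382, which left some named genes without a value. Precision was lowest for the 3238 genes with a mean log2 CPM under 0, whose intervals spanned a median of 21.6-fold to each side, with depth and spread between libraries not separated.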

Other observations

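The tests of other splits of the libraries, of list members varying together, of the list scores by genotype and of the most abundant genes and median levels of other cell type lists were chosen after the results were seen, and those of genes with few reads and of a low level of kdrl RNA alone before.

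The genes of this paragraph were chosen after their values were seen, and none passed the test. The matrix glycoprotein gene tnc stood at 50.8 ± 7.24 CPM in wild-type and 103 ± 40.8 CPM in mutant libraries (SD, n = 3 each), a log2 difference of 1.03 ± 0.26 (SE). The collagen gene col15a1b stood at 38.9 ± 14.6 and 88.3 ± 32.2 CPM (1.18 ± 0.33), the retinoic acid receptor gene rarga at 43.6 ± 2.75 and 67.9 ± 10.6 CPM (0.64 ± 0.17), the homeobox gene pitx1 at 29.1 ± 9.02 and 62.6 ± 30.6 CPM (2.15-fold, 95% interval 1.23 to 3.75) and cpla2 at 6.02 ± 1.00 and 14.2 ± 3.39 CPM (1.23 ± 0.31). The adjusted p of each was 1 in the edgeR quasi-likelihood test. Both papl and myo3a had 0 reads in each wild-type library. Their fitted 95% intervals began at 10.6-fold and 10.3-fold higher in the mutant libraries. By summed reads alone the bounds were at least 52.9-fold and 60.3-fold higher. Without wild-type 3 these bounds were 33.0-fold and 37.6-fold, and without mutant 3, which held 138 of the myo3a reads beside 24 and 32 in mutant 1 and 2, that of myo3a was 28.9-fold.

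In wild-type 1, 20.3% of entries were reads aligned to more than 1 place, against 13.6% to 15.0% in the other libraries. This library had 801 reads on 5.8S ribosomal RNA, against 92 to 179 elsewhere, and 2612 on signal recognition particle RNA, against 423 to 1054. The numbers of genes with 0 reads in every library of one genotype and at least 5 in each of the other were 49 for wild-type and 16 for mutant. Together these made 65, which include cx41.8, apobb, papl and myo3a. The other splits gave 70 to 135, so 10 of the 10 splits gave at least as many and the genotypes the fewest. Such genes were thus no more frequent between genotypes than between other groupings of the libraries.

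The most abundant gene of 10 of the 11 other cell type lists lay above kdrl in all 6 libraries. The gene lyz stood at 91.1 to 266 times, krt4 at 68.2 to 106 times and hbae3 at 17.8 to 56.6 times the level of kdrl. That count set the most abundant gene of a whole list against 1 endothelial gene, so it favours the lists and decides nothing by itself. The most abundant pan-endothelial gene, vsg1, had a mean of 117 CPM, below lyz, krt4 and hbae3 (5835, 3523 and 1499 CPM). It lay above the most abundant pigment cell gene, paics (83.6 CPM), and heart gene, atp2a2a (34.3 CPM). Levels such as that of lyz could come from cells or RNA of other types in the sorted material, despite a gate on EGFP. By the median of a whole list the order was mixed: the pan-endothelial list lay at percentile 81.9 of tested genes, the neutrophil, erythrocyte, skeletal muscle and epidermis lists higher (97.7, 89.7, 93.3 and 93.7) and the other 7 lower, from 18.8 to 70.7. Some leading genes, such as paics and nme2b.2, are used by many cell types, and the share of each list that endothelial cells also express was not measured here. The test for a low level of kdrl RNA alone decides nothing, because it set single endothelial genes against the most abundant gene of whole lists. In it, 0 of 30 pan-endothelial members exceeded the top gene of at least 6 of these lists, and their median was 39.7 CPM. By rank kdrl lay near the median of the pan-endothelial list (percentile 82.3 beside 81.9), so it was not low among these endothelial genes. No biological explanation was tested, since the levels were high in both genotypes.

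Fewer genes reached an unadjusted p under 0.05 than chance gives, 305 against 969. Genes with few reads are argued against as the reason. Among the 11382 genes with a CPM of at least 5 in at least 3 libraries the share was 1.52%, close to the 1.57% of all tested genes. The exact binomial interval of 1.30% to 1.76% takes genes as independent, which they are not, so it is too narrow. Differences between libraries that cut across genotype may account for part of it: 8 of the 9 other splits had more such genes, up to 2272 for wild-type 1, mutant 1 and mutant 2 against the rest, a structure of the samples in which ribosomal protein genes took at least 16.5% of reads in those 3 libraries and at most 15.3% in the others. The deficit was not particular to the genotypes, since 7 of the 9 other splits, with 294 to 880 such genes, also lay below the 969 of chance. With a real number of called genes of 0, all 10 splits give at least as many by construction (highest other 2), so that count decides nothing.

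The skeletal muscle and neural lists were lower in mutant libraries with the preset correlation, a call that both lost with an estimated correlation (adjusted p = 0.975 each, camera). Their members varied together within genotype, with a mean correlation of 0.756 for muscle and 0.2005 for neural genes. The 95th percentile of 1000 random lists was 0.0686 and 0.0529. Lists that were not called also varied together, such as the venous (0.630), neutrophil (0.601) and dissociation stress (0.413) lists, while others did not, such as mural and mesenchyme (0.008). Such variation is thus not particular to the called lists and does not by itself explain their calls. An amount of RNA from these cells that differs between libraries of one genotype remains only a candidate explanation. Genotype stays open, with exact two-sided permutation p-values of 0.6 and 0.3 for the list scores with libraries taken as unpaired, where 3 against 3 cannot go below 0.1. The number of shifted lists was 2 in the real split and up to 13 in the others, and 7 of the 10 splits gave at least as many. A count of 2 was thus not particular to genotype. Leaving out wild-type 2 ended both calls (means of -0.02 and -0.19), wild-type 1 or mutant 3 the muscle call (-0.32 and -0.11) and wild-type 3 or mutant 1 the neural call (-0.16 and -0.06), and 1 neural but 0 muscle members are in another list.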
